A study of Mus musculus with 6 samples.

How the data were processed

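ATAC-seq peak lists of long-term haematopoietic stem cells from 3 aged and 3 young C57BL/6 mouse samples were analysed, one list per sample. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, the genome build was mm10 and the tools included Bowtie2, SAMtools, Picard and MACS2; their versions, parameters and roles were not given in the sources used here, nor was any shift of reads for the transposase. The number of reads behind each list was not given either.

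Each deposited list holds, per peak, a start and end, a score, a fold enrichment, a -log10 p, a -log10 q and a summit position, in the layout that MACS2 writes. The lists have no header, so the units were checked on the values. In the deposited lists the score is 10 times the -log10 p, rounded down and capped at 1000. The deposited fold enrichment is a ratio of the peak over the background of the same sample, and the deposited -log10 p and -log10 q values belong to the peak and depend on the depth of that sample. All peaks had a p-value of at most 0.01 in the deposited lists, so weak peaks are included. These values are the authors' own and were used mainly to rank and filter peaks within a list, and most comparisons between lists were of presence, overlap and shares. Other comparisons use the values themselves: the ratio of median fold enrichment of X to autosomal peaks within a list, the median and the number of distinct fold enrichments, and counts of peaks at limits on q. The last 3 depend on the depth of the sample, which is unknown. Peaks were called per sample, as each list has its own boundaries, and no list was identical to another (0 of 15 pairs).

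Rows that repeat the interval of another row, as a peak with several summits does, were merged to distinct peaks. Chromosomes 1 to 19 and X were used; Y peaks are given apart. Peaks of all lists that overlapped by at least 1 bp were merged to 882758 regions, and a list called a region if one of its peaks overlapped it. Percentiles are ranks of the -log10 p within a list, with ties averaged; where a list was cut to its strongest peaks, ties were ordered at random with a fixed seed. Intervals on shares are 95% Wilson intervals over peaks.

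Genes came from a RefSeq table on GRCm38.p6, the assembly that mm10 names, with the start and end of each gene but no strand or transcripts. The planned promoter window around transcription start sites was therefore replaced by a window of 1 kb around both ends of the gene, for 21639 protein-coding and listed non-coding genes. Windows at annotated ends can miss a strong region of the gene, as for Kdm6a, and which promoter was in use was not tested. For this reason the strongest region of a gene was added after the gene-end results had been seen. It is the merged region within the gene and 1 kb around it with the highest mean percentile over all 6 lists, chosen without regard to age. A list without a call lowered that mean, so the choice favours regions called in many lists over regions open at one age. The model with gene length was also added then; it is a logistic regression of being called in all 6 lists on list membership and log gene length.

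The 18 lists of genes were fixed before the data were examined and all of their symbols matched the table: the X inactivation centre, escape from X inactivation, X-linked blood and immune genes, stem-cell identity, genes with RNA higher in aged stem cells, AP-1 and immediate early genes, inflammation and interferon, cell cycle and senescence, nuclear lamina and polarity, chromatin regulators, housekeeping, and markers of B cells, T and NK cells, myeloid cells, erythroid cells, megakaryocytes and platelets, mast cells with basophils and eosinophils, and endothelial and stromal cells. Named genes followed a rule that was also fixed then: every member of the first 2 lists; in the other lists, members called at one age alone and up to 4 with the largest difference in lists called; up to 10 age-specific genes per direction and up to 5 X regions per direction by their lowest percentile. Some genes that the rule takes are not reported here by name, though they count in their lists. Genes named for their strongest region were chosen after their values were seen.

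Single values were compared by exact 2-sided permutation tests and tables of regions or genes by 2-sided Fisher's exact tests (log2 X odds ratios of age-specific regions are given with 0.5 added to each count), with Benjamini-Hochberg adjustment over the 18 lists. Counts of age-specific regions and genes were set against the 9 other splits of the 6 lists. The counting of age-specific regions was tested on simulated calls over the 882758 regions with 200 planted regions per age. With every list calling its open regions, recovery of all 200 per age follows from the rule, so that step checks the code alone. At the rates of calling measured on regions that the 5 other lists shared, 74% of aged and 57% of young ones met the rule in a single random draw. Planted regions were given no calls in lists of the other age. These shares therefore follow from the rates of calling and leave out stray calls at the other age. Rates for weaker regions were not measured.

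Alternatives fixed beforehand were lists of equal length (110596 peaks), a -log10 q of at least 5, bins of 1 kb in place of merged regions, a gene-end window of 2.5 kb, leaving out each sample, and the replicate number as a block. Added after the data were seen were a q of at most 0.05, the strongest 5000, 10000 and 20000 peaks, a peak that covers at least 50% of the region, one end per gene, and the strongest region of a gene. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. No genome sequence was used here, so base content, mappability and motifs were not examined.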

Results

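Open chromatin was profiled by ATAC-seq, in which a transposase cuts accessible DNA and tags it for sequencing, in long-term haematopoietic stem cells of C57BL/6 mice. These rare marrow cells sustain blood formation and were sorted as lineage-negative cells that carry Kit and Sca1 and lack Flk2 and Cd34. The cells were kept overnight at 3% oxygen after sorting, and no sample without that step was analysed here. There were 3 aged and 3 young samples, each with its own list of accessible peaks on the mm10 assembly. The labels give neither the ages in weeks nor the sex of the animals, and they do not say whether the samples of an age came from separate animals, so p-values measure the spread between these samples, which may be technical. The aged lists held 244692, 129137 and 129949 distinct peaks (replicates 1 to 3) and the young lists 263956, 254869 and 110596. The titles carry a number before "exp" that the labels do not explain (10000, 2500 and 5000 for aged replicates 1 to 3, with 2500 and 5000 again for young replicates 2 and 3 and a number under 2500 for young replicate 1), so the lists may not be comparable in length or in rate of calling. Read depth was not given in the sources used here, and intervals on shares of peaks cover counting error only. With 3 lists per age, the smallest p an exact 2-sided permutation test can give is 0.1, so no comparison of single values could pass 0.05.

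The first question was which accessible regions the aged and young stem cells had in common. Several genes of the stem-cell identity list were called at both ages. Meis1, Runx1, Tal1, Erg, Hlf, Lmo2 and Mecom, all regulators of blood stem cells, had their strongest region called in each of the 6 lists. Other factors of that list were not: Hoxb5 was called in 1 aged and 2 young lists, Fli1 was missing in young replicate 2, and Gfi1 and Gfi1b were missing in aged replicate 3. The strongest region of Meis1 lay inside the gene (chromosome 11, 18924670 to 18925423) and ranked at a mean percentile of 96.9 within the lists. Of 34 stem-cell identity genes, 21 had their strongest region called in all 6 lists, against 7896 of all 21639 genes tested (Fisher's exact test over genes, adjusted p 0.0131). The odds ratio was 2.82, and with gene length in a logistic model it was 2.39 (95% interval 1.17 to 4.89, adjusted p 0.0506), so the call was lost near the threshold. Genes are not independent replicates, and the strongest region of a gene was chosen over all 6 lists without regard to age. That choice favours regions called in many lists, for every gene tested, so calls in all 6 lists are in part built in.

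Of the other lists, 4 were called in all 6 samples more often than other genes of their length. For AP-1 and immediate early genes, which cells switch on within minutes of a stimulus, this held for 18 of 25, among them Fos, Jun, Junb, Egr1 and Klf6 (length-adjusted odds ratio 6.71, adjusted p 0.00041). The overnight step at 3% oxygen applies to these and all other genes, and its effect could not be tested without samples that lack it. Nuclear lamina and cell polarity genes reached 14 of 18 (Lmna, Lmnb1, Sun1 and Cdc42 among them, adjusted p 0.0159), cell cycle and senescence genes 14 of 21 (including Cdkn1a, Cdkn1b and Trp53, adjusted p 0.0159), and housekeeping genes 13 of 15 (adjusted p 0.00257). Chromatin regulators reached 19 of 29, among them Smchd1, Ezh2, Eed, Dnmt1 and Dnmt3a, with an odds ratio of 3.31 (adjusted p 0.00761, Fisher's exact test) that became 2.61 with gene length in the model (95% interval 1.20 to 5.66, adjusted p 0.0506). Inflammation and interferon genes reached 13 of 28 (adjusted p 0.185), and genes whose RNA is known to rise in aged stem cells reached 11 of 36, including Vwf, Selp and Itgb3 (adjusted p 0.185). Over the 5 lists without young replicate 2, the chromatin regulators (adjusted p 0.0295) and the inflammation and interferon genes (adjusted p 0.0287) passed with gene length in the model, and the stem-cell identity genes did not (adjusted p 0.069). Of the 36 genes with RNA higher in aged stem cells, 22 were called in all 5. Their length-adjusted odds ratio was 1.18 there (adjusted p 0.693), against 0.561 over all 6 lists.

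Markers of mature cells were examined next. Of 18 myeloid genes only Csf1r, the receptor for macrophage colony-stimulating factor, had its strongest region called in all 6 lists. Mpo, Elane, Ctsg, Prtn3, S100a8 and S100a9, which encode granule and calcium-binding proteins of neutrophils and monocytes, were called in at most 3 lists each. The odds ratio for the myeloid list was 0.102 by Fisher's exact test (adjusted p 0.0147) and 0.142 with gene length in the model (95% interval 0.0187 to 1.08, adjusted p 0.133). Over the 5 lists without young replicate 2, 3 myeloid genes were called in all, with a length-adjusted odds ratio of 0.306 (adjusted p 0.111). The counts for other lineages were 2 of 14 B lymphoid genes (Dntt and Rag2), 2 of 16 T and NK genes (Lck and Gata3), 4 of 14 erythroid genes, 7 of 17 megakaryocyte and platelet genes, 1 of 11 mast cell, basophil and eosinophil genes (Mitf), and 2 of 15 endothelial and stromal genes (Flt1 and Pdgfrb). None of these 6 lists passed the length-adjusted test, where the smallest adjusted p among them was 0.0952 for the endothelial and stromal genes. The heat map of 4 gene groups shows the values behind these counts.

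**Figure D1:**
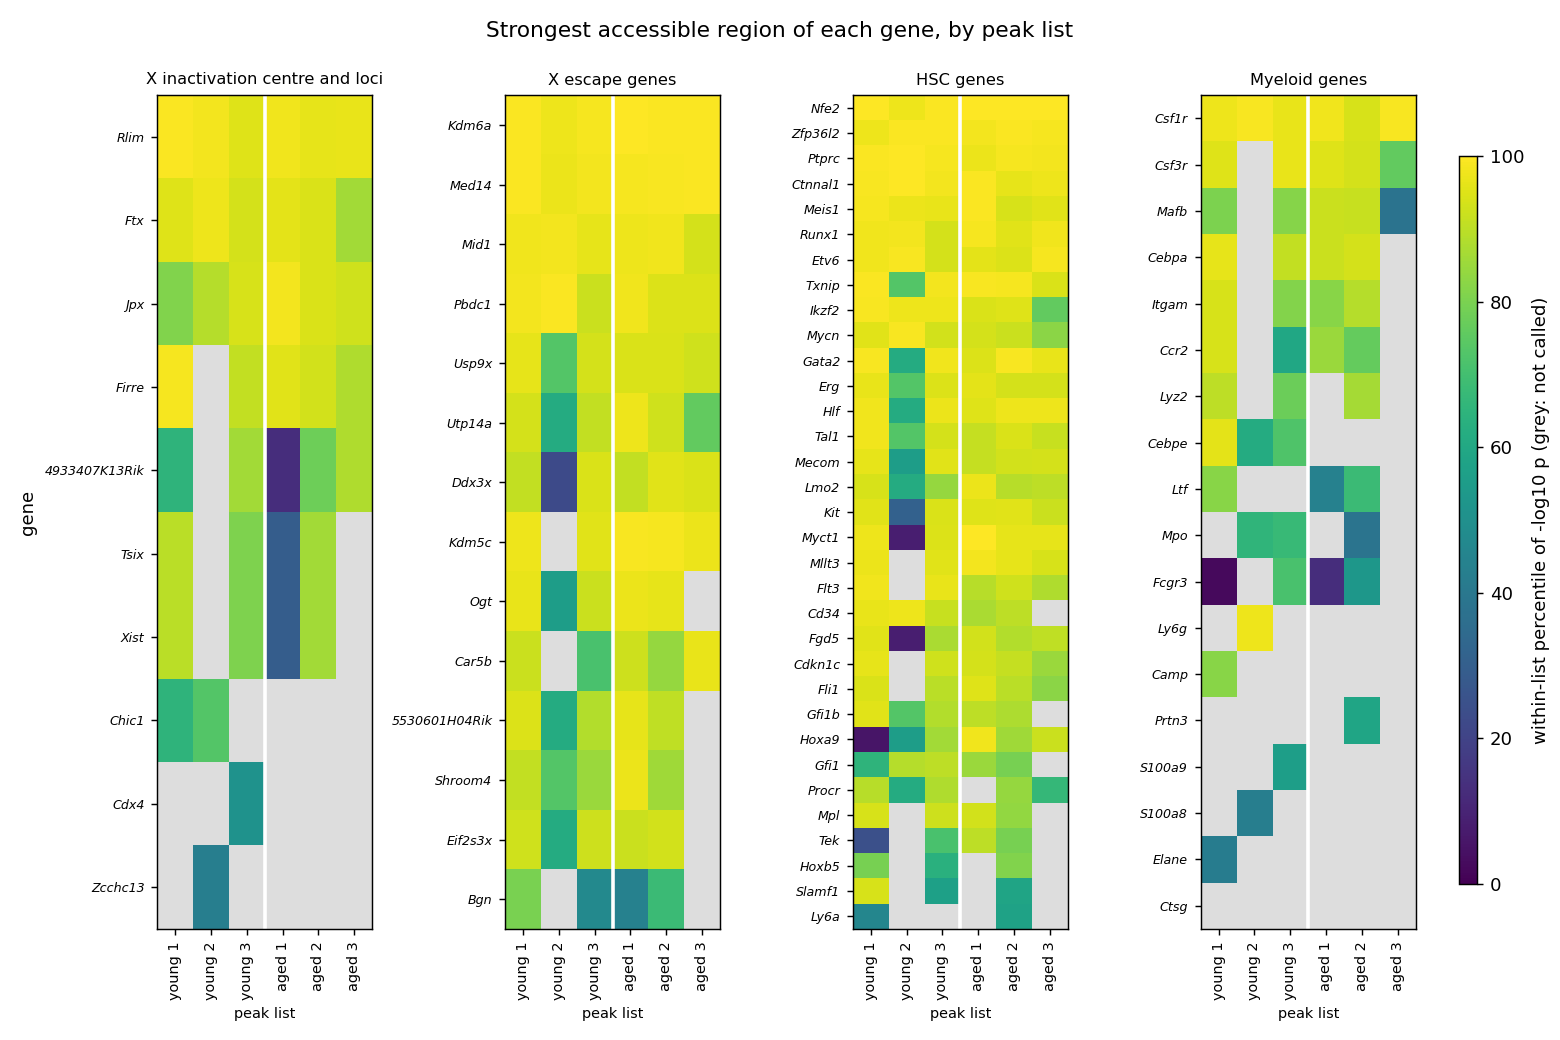
Within-list percentile of peak strength (colour, 0 to 100) of the strongest region of each gene (vertical axis) in the 3 young and 3 aged lists (horizontal axis), with grey where no peak was called and genes not reported here left out. Csf1r is the only one of 18 myeloid genes coloured in all 6 lists, and Meis1, Runx1 and Tal1 are among the stem-cell genes coloured in all 6.

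As whole lists, the samples did not group by age. The shared length of covered bases, as a Jaccard index, averaged 0.107 over the 9 pairs of an aged and a young list, 0.109 over the 3 aged pairs and 0.0766 over the 3 young pairs. The most alike pair was aged replicate 2 and young replicate 3, at 0.273. Peaks per list averaged 167926 ± 66482 in aged and 209807 ± 86039 in young samples (SD, n = 3 each, exact permutation p 0.7). The difference of -41881 was -2337 at q 0.05 and turned to 2836 at a -log10 q of at least 5. Young replicate 2 had 224 peaks with a -log10 q of at least 5, against 6005 to 31725 in the other lists, a count that depends on depth, and its Jaccard index with each other list was at most 0.0534. It called 62.3% of the regions that the 5 other lists shared, aged replicate 3 called 75.6%, and the 4 remaining lists called at least 97.4%.

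The title of the series concerns X chromosome inactivation in aged stem cells, so the share of accessible regions on X was compared next. No difference between ages was detected. X held 3.49% ± 0.507 of the peaks in aged and 3.86% ± 1.21 in young samples (SD, n = 3 each, exact permutation p 0.7). The single lists gave 4.05%, 3.05% and 3.38% for aged and 4.18%, 4.89% and 2.52% for young replicates 1 to 3, with 95% Wilson intervals no wider than 0.197 percentage points. X held 3.28% ± 0.487 of the covered length in aged and 3.74% ± 1.23 in young samples (SD, n = 3 each, exact permutation p 0.6). The median fold enrichment of X peaks over that of autosomal peaks within a list was 0.976 ± 0.0424 in aged and 0.978 ± 0.0298 in young samples (SD, n = 3 each, exact permutation p 1). In aged replicates 1 and 3 and young replicate 2 the X and autosomal medians were the same tied value, a ratio of 1. Fold enrichments took 17.2 distinct values per 1000 peaks in those aged lists and 0.785 in young replicate 2. The ratio could therefore not resolve small differences in these lists. Young replicate 2 decided the direction of the X share: without it the difference, aged minus young, moved from -0.37 to 0.141 percentage points, and without young replicate 3 it was -1.04.

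**Figure D2:**
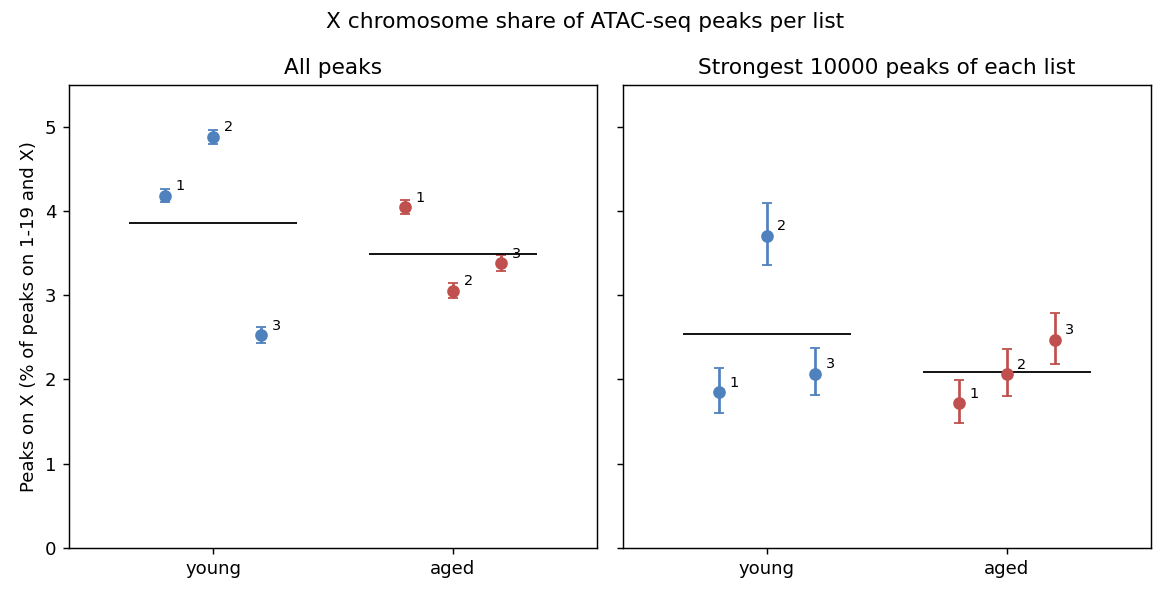
Percent of the peaks of each list that lie on X (vertical axis) in young and aged samples (horizontal axis), for all peaks (left) and for the strongest 10000 of each list (right), with 95% Wilson intervals, the replicate number beside each point and the group mean as a line. Young lists span 2.52% to 4.89% over all peaks and enclose the aged lists.

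Genes that are known to escape X inactivation did not differ detectably from all genes tested, most of them autosomal, in how often they were called. Of all 973 X-linked genes, the escape genes among them, 182 (18.7%) had their strongest region called in all 6 lists. The share was 50% for the escape genes, and a contrast with X-linked genes alone was not tested. Of 14 such genes, 7 had their strongest region called in all 6 lists, and 13 in at least 5 (length-adjusted odds ratio 1.22 for all 6, adjusted p 0.759). Kdm6a, a histone demethylase, had its strongest region at X, 18161932 to 18163245, inside the gene, at a mean percentile of 99.1. Med14, a Mediator subunit, followed at 98.6 (X, 12761640 to 12762579). Mid1, Pbdc1, Usp9x, Utp14a and Ddx3x completed the 7. Kdm5c was missing in young replicate 2. Ogt, 5530601H04Rik, Shroom4 and Eif2s3x were missing in aged replicate 3, Car5b in young replicate 2, and Bgn in both of these lists. Calls at the ends of the genes were similar, at 11.3 ± 2.89 of the 14 genes in aged and 13 ± 0 in young lists (SD, n = 3 each, exact permutation p 1), and the aged value was set by aged replicate 3, at 8. By gene ends, Kdm6a was called in young replicate 2 alone, and the centre of its strong region lies 1726 bp from the annotated end. The loci of the escape genes, with 10 kb on each side, held 0.0455% ± 0.00692 of the peaks in aged and 0.0583% ± 0.00503 in young lists (SD, n = 3 each, exact permutation p 0.1, the smallest possible). After adjustment over the 18 lists of genes that p was 0.953.

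At the X inactivation centre, Rlim, Jpx and Ftx, 3 of the 11 genes in the list, were called in all 6 lists. Against all genes tested, with gene length in the logistic model, the adjusted p was 0.489. Rlim encodes a ubiquitin ligase that promotes Xist transcription, and its strongest region (X, 103980695 to 103981774) had percentiles between 95.1 and 99.5. Jpx and Ftx are non-coding RNA genes next to Xist, with strongest regions at X, 103493254 to 103494057, and X, 103616723 to 103617353. Xist, whose RNA coats the silenced X, and its antisense gene Tsix shared one strongest region, at X, 103483090 to 103483401. It was called in aged replicates 1 and 2 and in young replicates 1 and 3, with percentiles of 29.3, 86.2, 89.7 and 80.5, and not in the lists with the lowest rates of calling. Over the whole Xist gene, the aged lists held 5, 4 and 0 peaks and the young lists 4, 3 and 3. Firre, an X-linked non-coding RNA gene that escapes silencing, held 18, 23 and 10 peaks in aged and 17, 13 and 24 in young lists. The other repeat-containing X locus in the list, 4933407K13Rik, held 3, 7 and 1 in aged and 7, 1 and 8 in young lists. By gene ends, Jpx, Rlim and Firre were called in all 6 lists, Xist, Chic1 and 4933407K13Rik in 2 of each age, Tsix, Ftx and Cdx4 in 1 of each, and Zcchc13 in 1 young list. Peaks of ATAC-seq without allele information cannot tell the active from the silenced X.

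Among 44 X-linked genes of blood and immunity, 19 had their strongest region called in all 6 lists, such as Pgk1, Atrx, Hprt and Smc1a. Against all genes tested, with gene length in the logistic model, the adjusted p was 0.754. A contrast of these 44 genes with X-linked genes alone was not tested. By gene ends, 6 of the 44 were called in more aged lists, 16 in more young lists and 22 in equal numbers. Aged replicate 3 carried this imbalance, with 22 of the genes called, against 32 and 33 in the other aged lists and 33 in each young list. Gata1, a regulator of red cell and platelet formation, was called in 1 aged and 3 young lists, and Alas2, an enzyme of haem synthesis in red cell precursors, in 2 aged and 0 young lists. By their strongest regions both turned, with Gata1 called in 2 aged and 0 young lists and Alas2 in 0 aged and 2 young lists. Tlr8 and Cd40lg were called in 2 young lists and 0 aged lists by either measure. X-linked genes as a whole were called less often than autosomal genes at both ages: the strongest region was called in all 6 lists for 182 of 973 X-linked genes (18.7%) against 37.3% of autosomal genes, with a length-adjusted odds ratio of 0.387 (95% interval 0.327 to 0.457). The share of X-linked genes called over that of autosomal genes was 0.667 ± 0.0546 in aged and 0.701 ± 0.0235 in young lists (SD, n = 3 each, exact permutation p 0.4).

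Regions called at one age and not at the other were counted next. Of 882758 merged regions, 443 were called in all 3 aged and no young list, and 537 in all 3 young and no aged list, while 9582 were called in all 6 lists. On X there were 6 and 14 of them (odds ratio 0.513, Fisher's exact test over regions, p 0.182). The aged-only X regions with the highest lowest percentile included X, 11931543 to 11931816, 36288 bp from the non-coding gene Gm52427, and X, 13555971 to 13556682, inside Cask, which encodes a membrane scaffold kinase. The young-only ones included X, 7168761 to 7169115, inside the chloride transporter gene Clcn5, and X, 169096971 to 169097424, inside Arhgap6. Exons and introns were not resolved with the annotation used. The X odds ratio rested on single lists. Its log2 value, with 0.5 added to each count, was -0.90 with all lists and 0.87 without aged replicate 2 (Fisher's exact p 0.00275). It was -0.91 without young replicate 1 (Fisher's exact p 0.0479) and -1.42 without young replicate 3 (Fisher's exact p 1.34e-06). Regions are not independent replicates, so these p-values do not measure the spread between samples. Without young replicate 3, the young-only regions were those of young replicates 1 and 2, the lists with the highest X shares (4.18% and 4.89%). The counts also changed with the list left out, but leaving out 1 list asks for fewer calls, so higher counts largely follow from the rule. Aged-only regions ran from 521 (without young replicate 2) to 6833 (without aged replicate 3). Young-only regions ran from 593 (without aged replicate 3) to 10257 (without young replicate 3).

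**Figure D3:**
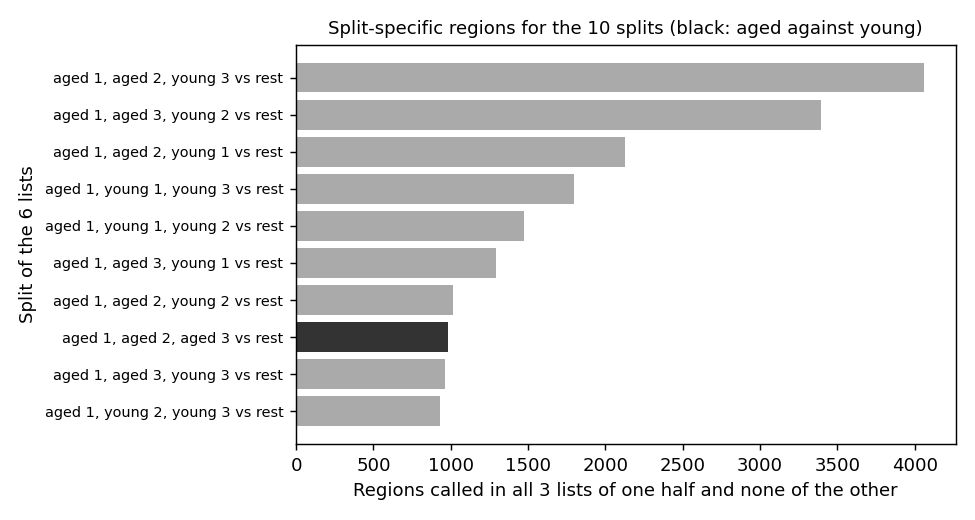
Number of regions called in all 3 lists on one side of a split and in none on the other (horizontal axis) for each of the 10 splits of the 6 lists (vertical axis), with the split by age in black. The split by age gives 980 regions, and the highest other split gives 4060, with aged replicate 3 and young replicate 2, the lists with the lowest rates of calling, on one side.

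Calls at gene ends gave named genes. Of 21639 genes, 45 had an end called in all 3 aged and no young list, and 62 in all 3 young and no aged list, while 7603 were called in all 6 lists. The highest-ranked aged-only genes were Galnt13, a glycosyltransferase (region at chromosome 2, 54436404 to 54436978), Lgals12, a galectin, Myo3a, an unconventional myosin, and Defb25, a beta-defensin. They were followed by Gm5916, the insulin-degrading enzyme Ide, the adhesion molecule Jaml, Nell2, the phosphatase subunit Ppp2r2b and Slc35d3. Galnt13 had percentiles of 71.6, 65.2 and 90.4 in the aged lists, and Nell2 and Ppp2r2b had 44.1, 53.1 and 51.4. Glod5 was the only X-linked gene among the aged-only ones (X, 8019482 to 8019652), and none of the young-only genes was X-linked.

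The young-only genes were led by Ociad2 (chromosome 5, 73338210 to 73338703, percentiles 90.2, 88.8 and 77.1), Tmem235, the melatonin receptor gene Mtnr1a, the neurotrophin receptor gene Ntrk3, and Serpinb1a, an inhibitor of neutrophil proteases. Next came Cebpe, a transcription factor of granulocyte maturation (chromosome 14, 54712828 to 54713265, percentiles 95.9, 61.5 and 72.3), Map10, Snx20, the homeobox gene Gsc and Gm19668. Galnt13, Tmem235 and Cebpe were also called at one age alone by their strongest region, a measure under which 24 genes were aged only and 26 young only. That measure favours regions called in many lists, so its counts cannot be set against those at gene ends. Leaving out 1 list asks for fewer calls, so higher counts largely follow from the rule. Aged-only genes at gene ends ran from 73 (without young replicate 2) to 179 (without aged replicate 2). Young-only genes ran from 89 (without aged replicate 3) to 350 (without young replicate 3). At q 0.05 the aged-only and young-only genes were 21 and 17. At a -log10 q of at least 5, a level that 224 peaks of young replicate 2 reached, they were 1 and 0.

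By the gene lists, 3 members were called at the ends in all young and no aged lists: Gata2, a stem-cell transcription factor, Cd22, a surface protein of B cells, and Cebpe. No member of the 18 lists was aged only. For Gata2 the end of the gene was called with percentiles of 47, 80.3 and 47.2 in the young lists. Its strongest region (chromosome 6, 88202802 to 88203667, inside the gene), a choice that favours shared regions, was called in all 6 lists. For Cd22 the strongest region was called in 2 aged lists and no young list, opposite to the end of the gene. In young replicate 1 the gene-end peaks of Gata2 and Cd22, at percentiles of 47 and 65, did not reach q 0.05. No list was enriched among the age-specific genes by Fisher's exact test (0 of 18 at an adjusted p of 0.05, 0 at an unadjusted p of 0.05, smallest adjusted p 0.769). When only the gene end called in more lists was used, the myeloid list passed (adjusted p 0.0367, Fisher's exact test) on 2 young-only members. These were Cebpe and Camp, an antimicrobial peptide gene of neutrophils. With both ends counted, Camp was called in 2 aged and 3 young lists, so it was young only because its other end was set aside. The choice of one end per gene was made after the data were seen.

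Other members differed by fewer lists. In the ageing list, Mmrn1, a platelet matrix protein gene, was called at its ends in 3 aged lists and 1 young list, and Fyb and Nid1 in 0 aged and 2 young lists. Irf7, an interferon response factor, was called in 3 aged lists and 1 young list, and Klf1, a factor of red cell maturation, in 2 aged and 0 young lists. Ccnd1, which drives entry into the cell cycle, Rag1, Prf1, Mcpt4 and Acta2 were each called in 0 aged and 2 young lists. Cd4, Lck, Tcf7, Tubb1, Rab27b and Pdgfrb were called in 1 aged and 3 young lists, and Emcn in 3 aged lists and 1 young list. Rac1, Sun2, Syne1 and Syne2, of the lamina and polarity list, were called in 3 aged and 2 young lists, as were Atf3 and Batf of the AP-1 list. Syne1 was missing in young replicate 1 and the 5 others in young replicate 2 alone, the list with the lowest rate of calling shared regions. In the whole AP-1 list, 5 members had more aged lists and 4 had more young lists. Dnmt1 and Dnmt3a ends were called in 1 aged and 0 young lists. By their strongest regions, Nid1 (2 aged, 0 young), Ccnd1, Acta2 and Tubb1 (2 aged, 1 young) turned direction. Fyb, Lck, Rab27b, Pdgfrb, Dnmt1, Dnmt3a, Rac1, Syne1 and Batf were called in all 6 lists by that measure, Klf1 in 2 of each age, and Rag1 and Emcn in 1 of each. Direction stayed for Mmrn1 and Irf7 (2 aged, 1 young), Sun2, Syne2 and Atf3 (3 and 2), Cd4 (1 and 2), Tcf7 (2 and 3), Prf1 (0 and 1) and Mcpt4 (0 and 2). In the stem-cell list, 2 members had more aged and 11 more young lists, and the aged replicate 3 list called 21 of its 34 members against 27 to 33 in the 5 others. No list of genes passed a test of the number of members called. The smallest p was that of the B lymphoid genes, with 5 ± 2.65 of 14 called in aged and 8.33 ± 0.577 in young lists (SD, n = 3 each, exact permutation p 0.1, the smallest possible, adjusted 1). By the strongest region this list turned direction, at 8 ± 3.61 in aged and 7.33 ± 1.53 in young lists (SD, n = 3 each, exact permutation p 1).

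The position of the peaks relative to genes did not differ detectably with age. Within 1 kb of a gene end lay 10.3% ± 2.38 of aged and 9.35% ± 4.55 of young peaks (SD, n = 3 each, exact permutation p 0.7, a difference of 0.912 points that ran from -3.37 at a -log10 q of at least 5 to 7.95 in the strongest 5000 peaks, and was negative without aged replicate 2, young replicate 1 or young replicate 2), elsewhere in gene bodies 41.5% ± 0.84 and 41.7% ± 1.2 (exact permutation p 1), and between genes 48.3% ± 2.79 and 49% ± 5.7 (exact permutation p 0.8). Across the chromosomes, the mean share of peaks, aged over young, was lowest for X, with a log2 ratio of -0.15, and the 19 autosomes ranged from -0.10 (chromosome 4) to 0.15 (chromosome 10). The aged and young lists did not overlap on chromosomes 4 and 10 (exact permutation p 0.1 each, the smallest possible, adjusted 1 over the 20 chromosomes), while X had an exact permutation p of 0.7. Without young replicate 2 the X value was 0.06.

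The X share was related to where the peaks of a list lay. Lists with a smaller share of peaks at gene ends had a larger share on X (Pearson r -0.972, exact permutation p 0.00139, adjusted 0.00417; Spearman rho -1, exact permutation p 0.00278, adjusted 0.00833, over 6 lists). Without the 2 lists farthest from the median r was -0.977, and 3 such relations were computed. Both shares come from the same peaks, and the number in the titles after "exp" joins only 1 aged and 1 young list each, too few for a value within it.

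**Figure D4:**
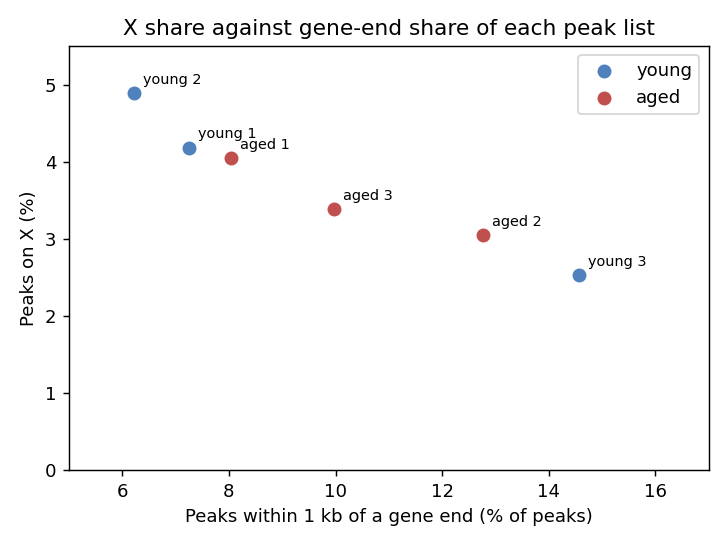
Percent of peaks on X (vertical axis) against percent of peaks within 1 kb of a gene end (horizontal axis) for the 6 lists, each point being one list. The points run from young replicate 2 (6.22% at gene ends, 4.89% on X) to young replicate 3 (14.6% and 2.52%), with the 3 aged lists between them.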

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

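The test at the male-specific genes was chosen after the Y peaks had been seen.

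Peaks on chromosome Y stand outside the comparisons of X and autosomes, and 5 lists held more of them than the 3 that a count of 0 allows. Aged replicates 1, 2 and 3 had 5, 5 and 4 distinct Y peaks, and young replicates 2 and 3 had 7 and 5, while young replicate 1 had 2. Of all 28 Y peaks, 24 lay in one stretch at the distal end of the chromosome (Y, 90732192 to 90745856), and the 4 others were in young replicate 2. Male cells in the sorted samples were tested as a source: the lists held 0 peaks within 1 kb of Ddx3y, Eif2s3y, Kdm5d and Uty, which are widely active in male cells, whereas the loci of their X-linked counterparts Ddx3x, Eif2s3x, Kdm5c and Kdm6a held a peak in 6, 5, 6 and 6 lists. This argues against male cells as the source of these peaks. Reads shared with a near-identical copy elsewhere in the genome remain open, since no genome sequence was used, and age was not tested as an explanation.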

How the results depend on the processing

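The limits of q 0.05, of 5000, 10000 and 20000 peaks and of 50% coverage, and the choices of one end per gene and of the strongest region, were chosen after the data were seen. Of 188 values under alternatives, 115 were differences or log ratios, of which 30 turned direction, and 73 were counts, of which 48 moved by over 1.5 times. The 115 include those with the replicate number as a block, which could not turn. The sizes of the differences were not held to a limit. The X odds ratio passed 0.05 in 3 values, 1 of them turned, by Fisher's exact tests over regions, which are not independent replicates. Where no cause is named below, the cause was not tested. No exact permutation test passed 0.05 under any alternative (smallest p 0.2), which this design could not have reached. The read depth, which is unknown, limits all presence calls. A 50% overlap of the shorter interval and a limit of 5 kb on peak width moved nothing, because peaks lie inside merged regions and the widest peak is 3246 bp, so both are void. At a -log10 q of at least 5 no X odds ratio could be had.

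Age-specific regions (443 aged, 537 young) became 271 and 162 in lists of equal length, 8 and 0 at a -log10 q of at least 5, 1157 and 1505 in 1 kb bins, 146 and 101 at q 0.05, 51 and 20 in the strongest 5000 peaks, 85 and 26 in 10000, 86 and 29 in 20000, and 185 and 203 with 50% coverage. Fewer peaks enter the shorter lists. Age-specific genes by gene ends (45 aged, 62 young) became 1 and 0 at a -log10 q of at least 5, 21 and 17 at q 0.05, 29 and 12 in the strongest 10000 peaks, 7 and 5 in 20000, and 24 and 26 by the strongest region; the young count was 30 in lists of equal length and 13 in the strongest 5000 peaks. One end per gene gave 1 enriched list, the myeloid genes, in place of 0, with Camp counted as young only although aged lists called its other end. The log2 X odds ratio, with 0.5 added to each count (-0.90), was 0.33 at q 0.05, 1.05 in the strongest 5000 peaks and 0.43 with 50% coverage.

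The log2 X to autosome ratio of peak strength, aged minus young (-0.00351), was 0.0574 in lists of equal length, 0.022 at a -log10 q of at least 5, 0.00334 at q 0.05 and 0.0774 in the strongest 5000 peaks. Peaks per list (-41881) were -2337 at q 0.05 and 2836 at a -log10 q of at least 5, the latter not among the values counted above. The gene-end share (0.912 points) was -3.37 at a -log10 q of at least 5 and 7.95, 5.63 and 4.6 in the strongest 5000, 10000 and 20000 peaks. Called regions per list (-41610) were 2850 at that limit. Called gene ends per list (-159) were 886 in lists of equal length, 1453 at a -log10 q of at least 5, 635 at q 0.05, 486, 659 and 1020.0 in the strongest 5000, 10000 and 20000 peaks, 67.3 with one end per gene and 223 by the strongest region.

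Leaving out each sample gave ranges of -1.04 to 0.141 points for the X share and -1.13 to 0.0845 for the covered length, both turned without young replicate 2. The log2 X value in the comparison of chromosomes (-0.15) ranged from -0.38 to 0.06, turned without the same list, and peaks per list from -91486.5 to -14806.5. The log2 strength ratio ranged from -0.0287 to 0.0331, the regions from 521 to 6833 aged and 593 to 10257 young, the log2 X odds ratio from -1.42 to 0.87, the genes from 73 to 179 aged and 89 to 350 young, the gene-end share from -0.652 to 3.52 points, and called gene ends from -1026 to 830 per list. With fewer lists, fewer calls are asked for. The X odds ratio turned without aged replicate 1 (0.17) and turned and passed 0.05 without aged replicate 2 (0.87, Fisher's exact p 0.00275). In the direction of all lists it passed without young replicate 1 (-0.91, Fisher's exact p 0.0479) or 3 (-1.42, Fisher's exact p 1.34e-06).

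Lists with the same replicate number also share the number after "exp" in their titles. Deviations of same-numbered lists correlated at 0.016, -0.156 and -0.164 over regions. The highest values were 0.188 for aged replicate 2 with young replicate 3 and 0.149 for aged replicate 3 with young replicate 2. The latter lists had the lowest rates of calling, so the check followed the rate of calling and cannot decide whether the samples were paired. With the replicate number as a block, the differences of means stay the same by construction, so their direction could not turn. The X share gave -0.37 (exact sign-flip permutation p 0.75, where 0.25 is the smallest possible), and no call changed.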

Other observations

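The gene families, the strongest region of each gene, the tests of list length, of weak background peaks, of age as the whole cause and of another cell type, and the splits of regions and of their X odds ratio were chosen after the result was seen.

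Gene families outside the lists described so far were described by the share of their gene ends called, and were not tested against each other. Ends of ribosomal protein genes were called for 91.2% ± 2.78 of 83 genes in aged and 88.4% ± 4.56 in young lists (SD, n = 3 each, exact permutation p 0.5). Proteasome subunit genes reached 89.2% ± 5.77 and 88.3% ± 11.8 of 40 genes (SD, n = 3 each, exact permutation p 1), subunits of NADH dehydrogenase, part of the respiratory chain, 88.3% ± 11.5 and 87.5% ± 10.9 of 40 (exact permutation p 1), and splicing factor genes 88.4% ± 5.02 and 89.9% ± 10 of 23 (exact permutation p 1). Hox genes, which pattern the body axis and in part act in blood stem cells, reached 54.7% ± 10.4 and 53.8% ± 7.69 of 39 genes (exact permutation p 1). Olfactory receptor ends were called for 21.4%, 9.01% and 11.3% of 1110 genes in the aged lists and for 22.4%, 22.1% and 6.58% in the young lists. Vomeronasal receptors reached 6.1% ± 2.82 and 11.1% ± 8.15 of 355 (exact permutation p 0.4), keratin genes 26.8% ± 9.41 and 27.7% ± 13.2 of 112 (exact permutation p 1), and beta-defensins 25.4% ± 13.1 and 30.2% ± 12.2 of 42 (exact permutation p 1). Of families largely or wholly on X, the reproductive homeobox genes of the Rhox cluster were called for 4.04% ± 7 and 15.2% ± 13.2 of 33 genes (exact permutation p 0.4), with none in aged replicates 2 and 3 and in young replicate 3, the Mage genes for 34.8% ± 11.4 and 33.3% ± 6.94 of 22, of which 20 lie on X (exact permutation p 1), and the Xlr and Slx families for 24.4% ± 7.7 and 26.7% ± 6.67 of 15, of which 12 lie on X (exact permutation p 1).

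The peak with the highest fold enrichment was the same 206 bp interval on X (87238286 to 87238491, inside Il1rapl1) in aged replicates 2 and 3 and young replicates 1 and 3, with values of 49.0, 23.6, 23.9 and 50.8 that are the authors' own. In aged replicate 1 it was a peak in Lars2, a mitochondrial leucyl-tRNA synthetase gene (chromosome 9, 123461787 to 123462257), and in young replicate 2 a peak on chromosome 8 (105827083 to 105827683). Of the regions called in 1 list, 4.58% lay on X, and of those called in all 6 lists, 2.15%. Lars2 held the region with the highest lowest percentile over the 6 lists. Mappability was not examined and no peaks were removed here for artefactual signal. Whether the Il1rapl1 and Lars2 peaks reflect open chromatin was therefore not tested.

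The spread of the X share between lists had 3 tested explanations. Age as the whole cause is argued against, since the 3 young lists span 2.36 percentage points and enclose the aged lists, while the means differ by -0.37. List length went with the X share (Pearson r 0.914, exact permutation p 0.0153, adjusted 0.0153; Spearman rho 0.943, exact permutation p 0.0167, adjusted 0.0167; r 0.916 without the 2 farthest lists), but as the whole cause it is argued against, because lists cut to equal length still spanned 2.24 points, and a part stays open. Weak background peaks may contribute: the X share went with the share of olfactory receptor ends called (Spearman rho 0.94, exact permutation p 0.0167, adjusted 0.0167; Pearson r 0.937, exact permutation p 0.00833, adjusted 0.0125; r 0.815 without the 2 farthest lists; 3 relations), but among the strongest 10000 peaks the span was still 1.99 points, with young replicate 2 at 3.71%, so background cannot be told apart from other causes. The span among the strongest 10000 peaks rested largely on young replicate 2, since the other lists held 1.72% to 2.47%. At a -log10 q of at least 5 the span was 0.98 points, but young replicate 2 had only 224 peaks there. A smaller effect of age stays open as untested.

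Young replicate 2 stood apart with 224 peaks at a -log10 q of at least 5 and a median fold enrichment of 1.92. Few reads behind the list may be the cause: its fold enrichments took 0.785 distinct values per 1000 peaks, against at least 11.7 in each other list, but its share of olfactory receptor ends was not the highest, which the test required, so this cannot be told apart from other causes. Cells of another type were tested by the ends of marker genes, where it called 79.4% of the stem-cell identity genes (95% Wilson interval 63.2 to 89.7) and at most 76.5% of the genes of another lineage, those of megakaryocytes and platelets, and the intervals are too wide to exclude them. Of its 224 strong peaks, 216 were called in at least 4 of the 5 other lists.

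With 10 splits of the 6 lists, no share of splits can fall under 0.05. As many age-specific regions as the 980 of the real split were seen in 8 of the 10. The highest other count was 4060, from the split of aged replicates 1 and 2 with young replicate 3 against the rest. Splits with aged replicate 3 and young replicate 2, the lists with the lowest rates of calling, on one side gave 1798 to 4060. Splits with these lists on opposite sides, the split by age among them, gave 928 to 1472. The 10 splits are therefore not alike, and such counts do not decide on age. For the X odds ratio of these regions, with 0.5 added to each count, the real split was the 1 with the largest log2 size (-0.90 against 0.63 for the highest other). For the number of age-specific genes by gene ends, 10 of 10 splits gave as many as the 107 of the real split, with 286 as the highest other. For the X value in the comparison of chromosomes, 7 of 10 gave as large a log2 ratio as -0.15, with 0.55 as the highest other.

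A higher rate of open gene ends on X in aged cells was tested as a hypothesis. The share of X-linked gene ends called over that of autosomal ones was 0.668 ± 0.0775 in aged and 0.709 ± 0.0371 in young lists (SD, n = 3 each, exact permutation p 0.7). The ranges overlapped, which had been set as the sign against the hypothesis, but with 3 lists per age an overlap does not exclude a smaller difference.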
